A study of Gallus gallus with 4 samples.

How the data were processed

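Breast muscle RNA of male broilers of a single line was compared on 4 two-colour microarrays. Per the labels, each array held RNA of low feed efficiency labelled with Cy3 in channel 1 and of high feed efficiency labelled with Cy5 in channel 2. This was read as 1 bird per channel, so 8 birds, but the sources used here do not say whether RNA was pooled. The labels gave 0 dye-swapped arrays, so dye and group cannot be told apart. Per the labels' protocols, total RNA was extracted with Trizol and 2 µg were used. The replicate number was taken from the sample title, which calls the 4 arrays biological replicates.

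The deposited values are log2 ratios of the dyes within each array, for 45220 features. The log2 scale was read from the values, whose commonest entries were logarithms of ratios of small whole numbers. Which dye was the numerator is not stated. The direction used throughout, high over low, is likely and not certain. It rests on the labels placing the high-efficiency bird in channel 2 and on channel 2 over channel 1 being the usual form. If the numerator was Cy3, every sign given here turns around. Scanner software, background correction and within-array normalization are not given in the sources used here, and the fluorescence of single dyes was not analysed here, so features could not be filtered on signal over background. The deposited medians of arrays 1 to 4 were -0.19, -0.49, -0.58 and -0.52 after the exclusions below. The deposited values were therefore not centred on the array median, and whether they were normalized in another way is not known.

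Between 4625 and 5576 features per array had an empty value. Between 107 and 157 per array sat at a ceiling of 16.61, the log2 of 100000, and were treated as not measured. After the values had been seen, 160 features whose deposited log2 ratio lay within 0.005 of 0 on at least 3 arrays were set aside too: 132 of them did so on all 4 arrays, 28 on 3 and 53 others on 2. This is the pattern of spots saturated in both dyes, which carry no measured ratio. That reading is an inference from the values and from the transcripts involved, such as GAPDH, LDHA and TPI1. No ratio is given for a gene measured by these features alone. The results with these features kept are given with the other alternatives. Saturation of a single dye cannot be seen in the ratios and would pull a value towards a deposited ratio of 1.

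A platform table named 4391 features with exactly 1 gene symbol (4046 symbols), 0 with several, and left 40829 unnamed here, among which control spots could not be told from others, so the feature counts include any such spots. The gene counts use named features only. Symbols were updated through a unique synonym in the RefSeq gene table of assembly GRCg7b for 405 symbols, 19 features with an ambiguous older symbol kept it, and no coordinates were used. Of 31722 features with a value on all 4 arrays, 11.7% had a symbol, giving 3494 genes. The gene value was the mean over its features, and 201 genes had more than 1. In 86 of those genes the features had both signs, and in 0 were they called in opposite directions.

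Each array was centred on its median. An intercept-only model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to features and to genes and tested against 0, two-sided, with Benjamini-Hochberg adjustment at 0.05. The p-values measure the spread between the 4 arrays, which is a spread between pairs of birds only if RNA was not pooled. A dye effect alike on all arrays lies outside this spread. Of 25 gene lists fixed before the data were examined, 23 had at least 5 measured members and were tested with camera at a preset correlation between genes of 0.01, adjusted over the 23. Camera with an estimated correlation and fry were run beside it. The adipocyte and the nerve and Schwann cell lists each had 4 measured members and were not tested. The genes named were fixed by rule before the data were examined: among genes with the same sign on all 4 arrays, the 12 highest and the 12 lowest mean ratios at adjusted p under 0.05, and up to 4 members per list with the smallest p. Any other gene named was chosen after its values were seen.

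The model was tested on simulated data with the real spread of each feature or gene. With 200 of 3494 genes changed, 49.0% of 1.5-fold and 74.0% of 2-fold changes were recovered with 10 false calls. With 200 of 31722 features changed, 0% were recovered at either size, and with 2000 changed, 33.1% and 55.6% were recovered with 57 false calls. A simulated 2-fold fall of all measured members of the slow sarcomere list was called, with 0 other lists. The simulated genes varied independently, so this does not test camera where genes are correlated.

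Alternatives were values as deposited, arrays scaled to the same median absolute deviation, quantile normalization, robust variance moderation, an unmoderated one-sample t statistic, array weights, other thresholds, values on at least 3 arrays, the median over features or genes with a single feature, camera on ranks, and leaving out each array in turn. Chosen after seeing the data were centring on the median of the 25% of features with the smallest SD, keeping the ceiling values, keeping the features at a ratio of 1, subtracting the median of a 5 by 5 neighbourhood in a grid of 85 columns, and testing lists among genes of lower SD. The grid was inferred from a correlation between features 85 places apart (r 0.11 to 0.12). The correlation was similar 170 places apart (0.11 to 0.13) and lower 1 place apart (0.03 to 0.05). For these arrays, their number of 4 limits the precision.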

Results

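The study addressed which transcripts in breast muscle differ between broilers that gain much and little weight per unit of feed. Gain and feed intake of individually fed males were measured from 6 to 7 weeks of age on a corn and soy diet with about 20.5% protein and 3280 kcal per kg. By the reading of the labels used here, the muscle of 4 birds of high and 4 birds of low feed efficiency was compared. There were 4 two-colour arrays, with 1 bird of each kind per array. Values are log2 ratios with the array median at 0, given as mean ± SD over the arrays (n = 4). A positive value likely means higher in the high-efficiency bird, because the labels place that bird in channel 2 (Cy5) and channel 2 over channel 1 is the usual form of such ratios. Between 39376 and 40278 features per array were measured. Over 31722 features with a value on every array, ratios correlated between arrays with Pearson's r of 0.15 to 0.19 and over 3494 named genes with 0.20 to 0.31, across features and genes that are not independent replicates. Spearman's correlations were 0.24 to 0.30 over features and 0.38 to 0.49 over genes.

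Among named genes, which 11.7% of the features measured on every array represent, the largest differences were in genes that were lower in the high-efficiency muscle. PPP1R1C, an inhibitor subunit of protein phosphatase 1, was 6.77-fold lower (-2.76 ± 0.16, adjusted p = 0.00193). MYL3, the ventricular and slow-muscle essential light chain, was 6.32-fold lower (-2.66 ± 0.20) and CSRP3, the muscle LIM protein, 5.79-fold lower (-2.53 ± 0.08). The slow and cardiac myosin heavy chains MYH7B (-2.52 ± 0.82) and MYH15 (-2.28 ± 0.06, named MYH6 on the platform) followed. Also among the 12 lowest were phospholamban, PLN (-2.02 ± 0.04), slow myosin-binding protein C, MYBPC1 (-1.78 ± 0.25), and the actin filament protein LMOD2 (-1.63 ± 0.22). The remaining 4 of the 12 were CLEC3A (-2.15 ± 1.06), ZNF593 (-2.10 ± 1.17), the vesicular monoamine transporter SLC18A2 (-1.98 ± 1.08) and the NADPH oxidase organizer NOXO1 (-1.46 ± 0.76). ZNF593 did not pass with arrays centred on the least variable features (adjusted p = 0.051).

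The 12 highest named genes differed by less. Ribosomal protein gene RPS24 was 2.14-fold higher (1.10 ± 0.07) and GSTZ1, an enzyme of tyrosine breakdown, 2.12-fold higher (1.09 ± 0.07). The membrane-bound carbonic anhydrase CA4 (1.05 ± 0.16), the secreted C1QTNF3 (1.02 ± 0.13) and METTL7A (1.01 ± 0.05) were also over 2-fold higher. THRSP, a thyroid hormone responsive regulator of lipid synthesis, stood at 0.89 ± 0.04 and the retinoid carrier RBP7 at 0.89 ± 0.15. The others were the splicing factor BUD31 (0.94 ± 0.08), MRRF, a mitochondrial ribosome recycling factor by its platform symbol (0.90 ± 0.04), the histone methyltransferase SETDB1 (0.88 ± 0.08), proenkephalin, PENK (0.85 ± 0.05), and the antiproliferative TOB1 (0.84 ± 0.12). These 12 genes kept a positive ratio under every centring. This had to be so, since the other centrings lower all genes by less than these ratios. Values were lower without centring (RPS24 0.65), where RBP7 (adjusted p = 0.0597), SETDB1 (0.0563) and TOB1 (0.0766) did not pass.

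In all, 861 of 3494 genes passed the limma test, 648 higher and 213 lower, and 1258 of 31722 features, 880 higher and 378 lower. Of the called genes, 5 were over 2-fold higher and 26 over 2-fold lower. Over all called features, 177 were over 2-fold higher (5 of them with a symbol) and 116 over 2-fold lower (17 with a symbol). Of the higher ones, 107 lay between 1.91 and 2.36 with a median SD of 0.08, 6 lay between 3.05 and 3.81, and 0 of these had a symbol. Their deposited medians were 1.73 and 3.28, close to ratios of 3 and 10 at which control RNAs are commonly added. With the array median at 0 they were 2.17 and 3.72, further from those ratios. What these features measure is not given in the sources used here. Outside these 2 groups 1145 features passed, 767 higher, with 64 over 2-fold higher. These counts leave out possible controls on the higher side only. The 116 features over 2-fold lower, with a deposited median of -1.62, were not searched for such groups. The 64 and the 116 are therefore not a like comparison. The balance of directions depended on the centring. With arrays centred on their least variable features, 280 genes were higher and 343 lower, and without centring 9 were higher and 1142 lower. The median over all genes was 0.01 with the array median at 0, -0.12 with the least variable features at 0 and -0.43 as deposited, so each ratio is relative to that choice. Both other centrings lower all genes alike, so only higher calls were open to loss of their sign. Of the 648 genes called higher, 280 were also called higher with the least variable features at 0, and 9 under all 3 centrings. Without array 1, 2, 3 and 4 the gene calls numbered 404 (299 higher), 4 (0 higher), 5 (0 higher) and 198 (144 higher). The feature calls numbered 142 (134 higher), 120 (109), 120 (112) and 123 (114).

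**Figure D1:**
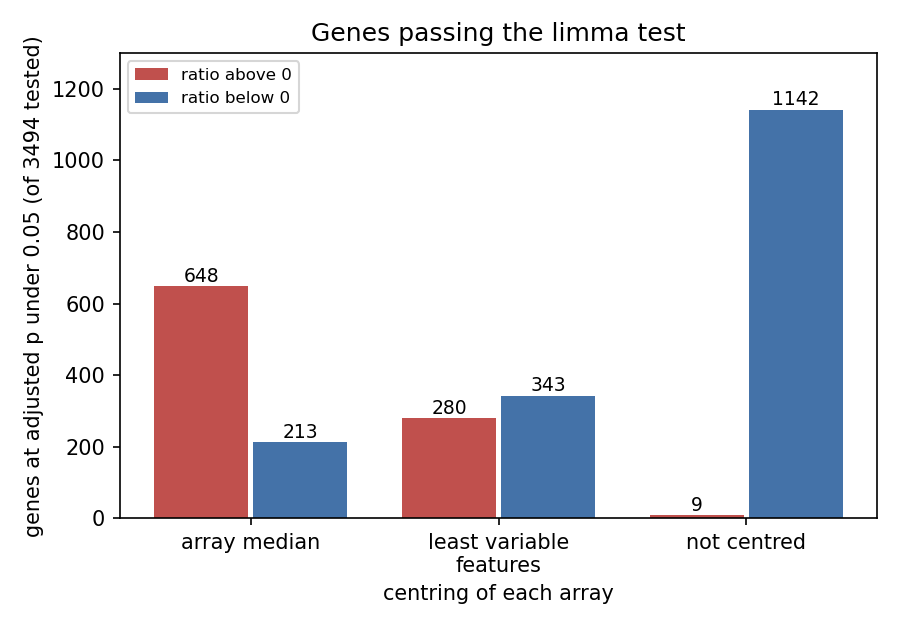
Number of the 3494 named genes at adjusted p under 0.05 (vertical axis), split by the sign of the ratio, for 3 ways of centring the arrays (horizontal axis). Genes with a ratio above 0 numbered 648 with the array median at 0, 280 with the least variable features at 0 and 9 without centring.

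Genes of slow and cardiac-type muscle fell together. Of the 13 measured members of that list, 10 fell, 0 rose and 3 did not pass (1 higher and 11 lower adjusted over the list alone), with a median of -0.75 and array medians from -0.75 to -1.01. Besides the genes above, slow troponin I, TNNI1 (-1.43 ± 0.10), the slow and cardiac calcium pump ATP2A2 (-0.75 ± 0.07), cardiac myosin-binding protein C, MYBPC3 (-0.69 ± 0.19), the embryonic and atrial light chain MYL4 (-0.68 ± 0.35) and cardiac troponin T, TNNT2 (-0.59 ± 0.04) fell. MYH7 (0.72 ± 0.58), MYL2 (-0.27 ± 0.35) and TPM3 (-0.18 ± 0.07) did not pass. The list shift was called by camera (adjusted p = 1.3e-08), with adjusted p = 0.164 with an estimated correlation, and the median was -0.88 and -1.19 under the other centrings, which lower all genes (with 11 and 12 members lower and 0 higher). The fast-type list showed no shift (adjusted p = 0.991): of 7 measured members, fast troponin T, TNNT3, rose (0.41 ± 0.07, but -0.03 without centring) and parvalbumin, PVALB (-0.96 ± 0.15), and myotilin, MYOT (-0.36 ± 0.14), fell, with 3 higher and 2 lower adjusted over the list alone, and 0 higher and 3 lower without centring. TNNC1, CASQ2 and TPM1 were at a ratio of 1 and were not measured here. Only 7 of 24 listed fast-type genes were measured, with no fast myosin heavy chain among them, against 13 of 23 slow and cardiac-type genes.

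**Figure D2:**
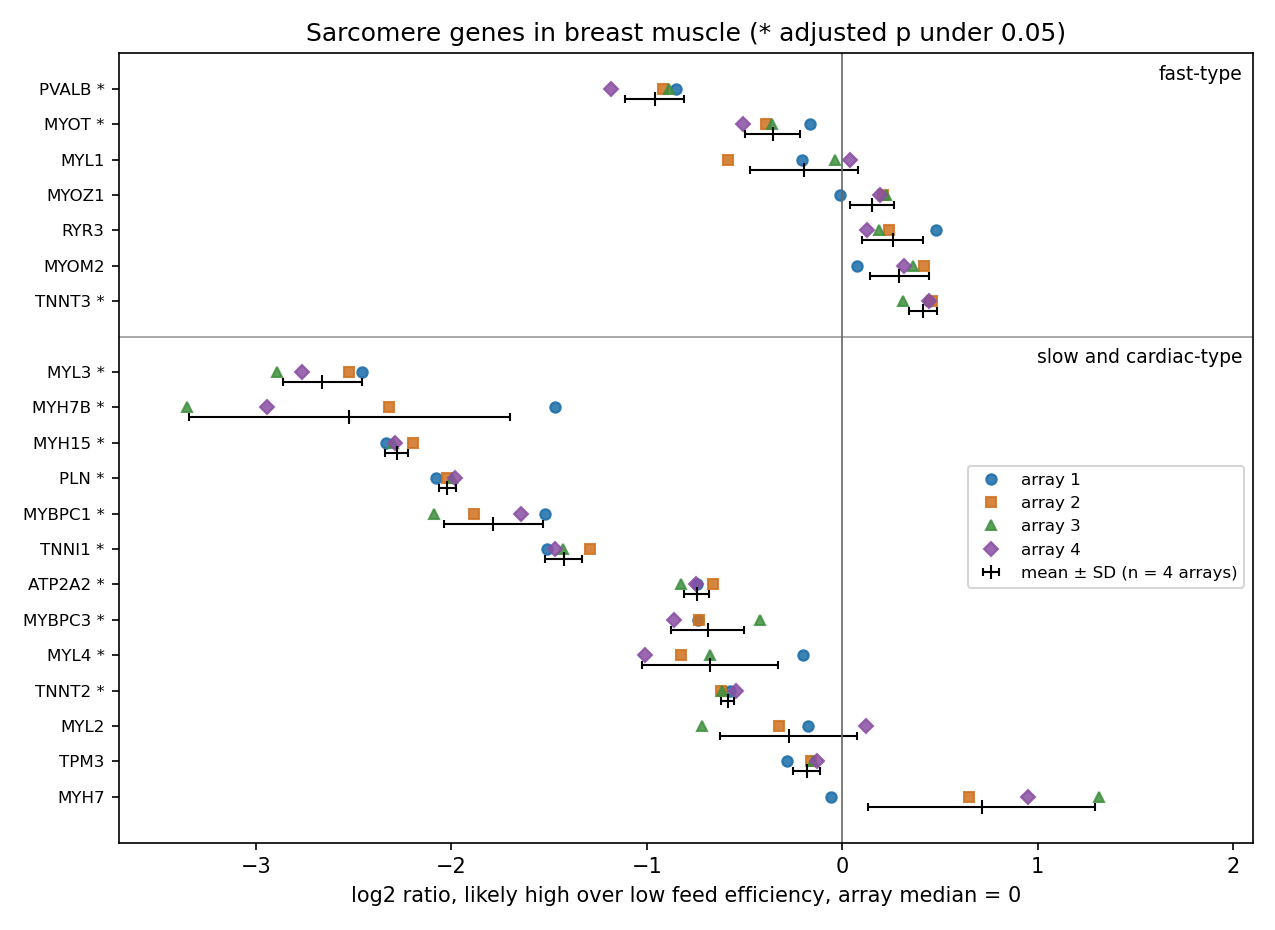
Log2 ratio (horizontal axis) of each measured member of the slow and cardiac-type and of the fast-type sarcomere list (vertical axis). Points are the 4 arrays, bars the mean ± SD, and stars genes at adjusted p under 0.05. PLN lies near -2.02 and MYH15 near -2.28 on every array, while MYH7B ranges from -1.47 to -3.35.

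Mitochondrial genes stood above the array median. In the complex I list, whose products form the first enzyme of the respiratory chain, 8 of 10 measured genes rose and 0 fell (9 higher adjusted over the list alone), with a median of 0.26 and NDUFB10 at 0.67 ± 0.07, NDUFS3 at 0.36 ± 0.03, NDUFC2 at 0.32 ± 0.08 and NDUFA9 at 0.24 ± 0.04. In complexes II to V, 4 of 7 rose and 0 fell (5 higher adjusted over the list alone), among them COX7A2L (0.57 ± 0.05), which helps join respiratory complexes, and the ATP synthase subunits ATP5J2 (0.50 ± 0.03) and ATP5H (0.36 ± 0.10). SDHD, a subunit of complex II, stood at 0.21 ± 0.04. Of mitochondrial biogenesis and carrier genes, 7 of 12 rose and 0 fell (7 higher adjusted over the list alone), including the outer membrane channels VDAC1 (0.61 ± 0.06) and VDAC2 (0.59 ± 0.02), the mitochondrial DNA-binding protein SSBP1 (0.48 ± 0.04) and the mitochondrial transcription factor TFAM (0.41 ± 0.05). Camera called these 3 lists (adjusted p = 0.00215, 0.0198 and 0.032), with adjusted p = 0.258 with an estimated correlation for each. Among genes of lower SD these lists were not called. With the least variable features at 0, only 2 of 10, 2 of 7 and 5 of 12 genes of these lists rose and 1 of the biogenesis list fell. There NDUFC2 (adjusted p = 0.0673), NDUFA9 (0.141), ATP5H (0.0655) and SDHD (0.219) did not pass. Without centring 0 genes of the 3 lists rose by limma and 3 of the biogenesis list fell. The medians of these lists were then -0.18, -0.19 and -0.24, NDUFS3, NDUFC2, NDUFA9, ATP5H, SDHD and TFAM turned negative, and the biogenesis list was not called (adjusted p = 0.0555). That list was also not called without array 1 (adjusted p = 0.088) or array 4 (adjusted p = 0.0714).

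Genes of protein synthesis and breakdown were above the array median as well. Among translation factors 10 of 16 rose and 0 fell (10 higher adjusted over the list alone; median 0.25), with EEF1E1 at 0.57 ± 0.05, the initiation factor subunits EIF2S3 at 0.46 ± 0.06 and EIF2S1 at 0.42 ± 0.07, and EIF3E at 0.40 ± 0.04. Of 14 measured ribosomal protein genes 5 rose and 0 fell (6 higher adjusted over the list alone; median 0.26), with RPS24, RPL14 (0.59 ± 0.13), RPL37 (0.51 ± 0.09) and RPL36 (0.51 ± 0.04) leading, while 14 genes of this list had features at a ratio of 1, 2 of them also measured by another feature. Of 18 ubiquitin and proteasome genes 11 rose and 0 fell (13 higher adjusted over the list alone; median 0.27), among them the proteasome subunits PSMA6 (0.55 ± 0.12), PSMC5 (0.54 ± 0.02), PSMB1 (0.49 ± 0.06) and PSMC1 (0.35 ± 0.03). Camera called the translation (adjusted p = 0.00215), ribosomal (0.0198) and proteasome (0.00223) lists, with adjusted p = 0.258, 0.278 and 0.258 with an estimated correlation. They were not called among genes of lower SD. With the least variable features at 0, 5 translation, 5 ribosomal and 4 proteasome genes rose and 0 fell. Without centring 0, 1 and 0 rose and 1, 1 and 3 fell. The medians of the 3 lists were then -0.19, -0.18 and -0.17, and EIF3E, EIF2S1 and PSMC1 turned negative. With values on at least 3 arrays the ribosomal list was not called (median 0.14, adjusted p = 0.197).

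Among metabolic genes the directions were mixed. LDHB, the heart-type lactate dehydrogenase subunit, fell 1.98-fold (-0.99 ± 0.08). A feature of muscle phosphofructokinase, PFKM, fell 1.66-fold (-0.73 ± 0.31), while the phosphorylase kinase subunit PHKB (0.65 ± 0.10) and hexokinase HK1 (0.49 ± 0.05) rose. The glycolysis and glycogen list had 2 of 10 measured members higher and 2 lower (2 and 3 adjusted over the list alone), no shift (adjusted p = 0.484), and 8 genes with features at a ratio of 1, among them GAPDH, TPI1, LDHA and a second PFKM feature. In fatty acid uptake and oxidation 4 of 18 rose and 3 fell (5 and 3 adjusted over the list alone): the fatty acid carrier FABP4 (0.79 ± 0.06) and the uncoupling protein UCP3 (0.44 ± 0.10, and 0.00 without centring) rose, and the β-oxidation enzymes DECR1 (-0.57 ± 0.21) and HADHA (-0.34 ± 0.12) fell, with no list shift (adjusted p = 0.991). Of 7 citric acid cycle and pyruvate genes 5 rose and 1 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.0762). Its examples were the pyruvate dehydrogenase kinase PDK3 (0.57 ± 0.12), SUCLG2 (0.36 ± 0.13), IDH3A (0.34 ± 0.08) and PDHB (0.27 ± 0.04), the last 3 below 0 without centring and not passing with the least variable features at 0 (adjusted p = 0.0845, 0.0674 and 0.0964). In lipid synthesis 4 of 8 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.244). They were THRSP, the lanosterol synthase LSS (0.49 ± 0.14), malic enzyme ME1 (0.32 ± 0.05) and HMGCS1 (0.29 ± 0.05), of which ME1 and HMGCS1 were below 0 without centring. With the least variable features at 0 the higher and lower genes numbered 2 and 2 in glycolysis, 2 and 4 in fatty acid, 1 and 1 in citric acid cycle and 2 and 0 in lipid synthesis genes. Without centring they numbered 0 and 6, 0 and 8, 0 and 1, and 1 and 1.

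Myogenic and growth genes held 7 higher and 1 lower of 24 (7 and 2 adjusted over the list alone; adjusted p = 0.693). The myogenic transcription factors MYOD1 (0.53 ± 0.04) and MYF6 (0.58 ± 0.11) and the receptor FGFR1 (0.57 ± 0.04) rose, against the fall of CSRP3. In the cytoskeleton and Z-disc list 6 of 18 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.693): the actin-capping CAPZA2 (0.71 ± 0.10), the tropomodulin TMOD4 (0.55 ± 0.04) and synemin, SYNM (0.49 ± 0.04), rose, and TMOD1 fell 2.13-fold (-1.09 ± 0.10). In energy sensing and insulin signalling 2 of 12 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.693). These were the adaptor GAB1 (0.34 ± 0.10) and the mitochondrial deacetylase SIRT3 (0.26 ± 0.03), both below 0 without centring. FOXO1 (0.19 ± 0.09) and the insulin receptor INSR (-0.40 ± 0.37) did not pass. With the least variable features at 0 the higher and lower genes of these 3 lists numbered 4 and 2, 5 and 2, and 0 and 1. Without centring they numbered 0 and 6, 0 and 7, and 0 and 5.

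Among stress genes, 10 of 21 heat shock and chaperone genes rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.0762). The co-chaperones DNAJA2 (0.44 ± 0.05) and BAG3 (0.39 ± 0.06) rose but were below 0 without centring, and HSP90AB1 (-0.48 ± 0.13) and the heat shock factor HSF2 (-0.43 ± 0.11) fell. Antioxidant genes had 5 higher and 1 lower of 16, with the same counts adjusted over the list alone (adjusted p = 0.197): GSTZ1, GSTA2 (0.53 ± 0.17) and the peroxiredoxin PRDX1 (0.49 ± 0.12) rose and the extracellular superoxide dismutase SOD3 (-0.42 ± 0.02) fell. In autophagy, lysosome and calpain genes 4 of 14 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.518). They were the muscle calpain CAPN3 (0.47 ± 0.11) and BNIP3 (0.35 ± 0.10), ATG3 (0.32 ± 0.07) and ATG5 (0.30 ± 0.08), the last 3 below 0 without centring. These counts depended on the centring: with the least variable features at 0, 2 heat shock genes rose and 2 fell, 3 antioxidant genes rose and 1 fell, and 1 autophagy gene rose and 0 fell. Without centring the counts were 0 and 5, 1 and 3, and 0 and 4.

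Markers of leukocytes had a list median of -0.25, called by camera (adjusted p = 0.0119) but with adjusted p = 0.258 with an estimated correlation. Of 13 measured members 2 fell, with the same count adjusted over the list alone, and 0 rose: CD83, of activated dendritic and B cells (-0.50 ± 0.04), and the immunoglobulin joining chain JCHAIN (-0.73 ± 0.29). The macrophage receptor MARCO (-0.49 ± 0.30) and lysozyme, LYZ (-0.25 ± 0.13), did not pass. Inflammation and interferon genes had 1 higher and 3 lower of 25 (1 and 2 adjusted over the list alone; adjusted p = 0.106): the cytokine IL15 rose (0.62 ± 0.12), and the chemokine IL8L1 (-0.95 ± 0.51), PTGS2 (-0.34 ± 0.10) and SOCS3 (-0.25 ± 0.06) fell. Fibroblast and matrix markers had 2 higher and 3 lower of 22 (3 and 5 adjusted over the list alone; adjusted p = 0.25), with periostin, POSTN (0.57 ± 0.04), higher and thrombospondin 2, THBS2 (-1.22 ± 0.50), OGN (-0.46 ± 0.11) and COL6A1 (-0.34 ± 0.04) lower. Endothelial and smooth muscle markers had 1 higher and 1 lower of 9, with the same counts adjusted over the list alone (adjusted p = 0.383): FLT4 stood at 0.33 ± 0.12, below 0 without centring, and ACTA2 at -0.36 ± 0.09. SMTN (-0.26 ± 0.13) and CLDN5 (-0.28 ± 0.23) did not pass. Of 5 erythroid markers the α-globin HBA1 stood at 0.43 ± 0.02, and at -0.01 without centring, while HBE1 (-0.39 ± 0.32), HBZ (-0.80 ± 0.91) and EPB41 (-0.21 ± 0.48) did not pass (adjusted p = 0.693). With the least variable features at 0 the higher and lower genes numbered 0 and 4 among leukocyte, 1 and 4 among inflammation, 1 and 6 among fibroblast, 0 and 2 among endothelial and 1 and 0 among erythroid genes. Without centring they numbered 0 and 9, 0 and 12, 0 and 10, 0 and 3, and 0 and 2.

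**Figure D3:**
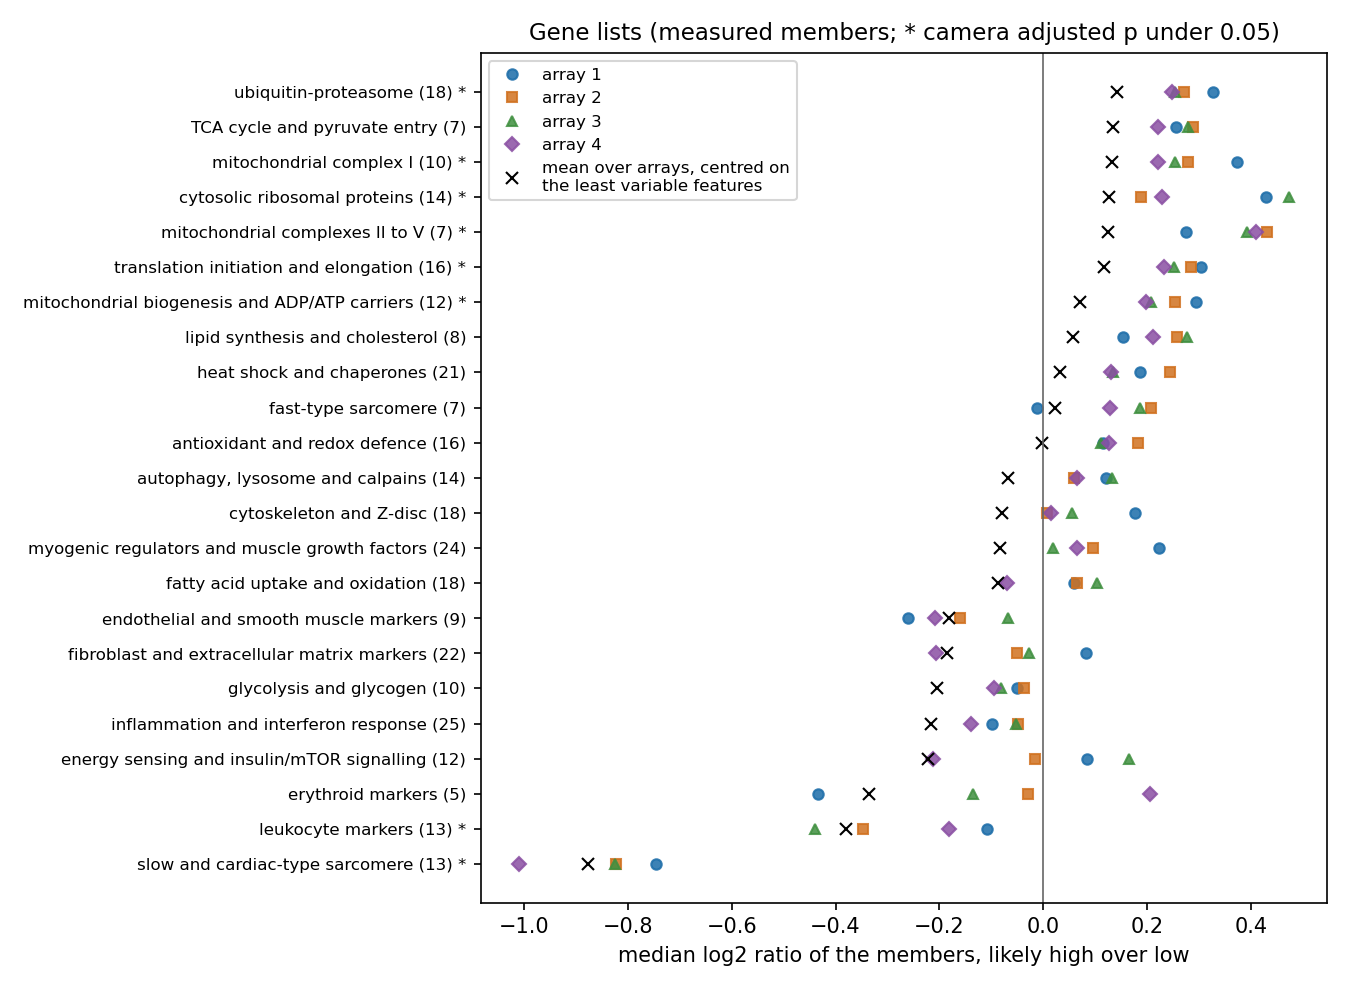
Median log2 ratio (horizontal axis) of the measured members of each of the 23 gene lists (vertical axis, number of members in brackets). Points are the 4 arrays with the array median at 0, crosses the median with the least variable features at 0, and stars lists at camera adjusted p under 0.05 with the preset correlation. The slow and cardiac-type list lies at -0.745 or below on every array, and the medians of the 6 lists called higher fall to between 0.07 and 0.14 with the least variable features at 0.

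With an estimated correlation 0 of the 23 lists passed (4 at an unadjusted p under 0.05), against 8 with the preset correlation and 14 with fry, which asks whether a list's genes move on balance one way. Median, mean and camera direction differed in sign for the fast-type list (0.15, -0.06 and down) and for the myogenic list (0.05, -0.07 and up), neither of which passed. Dye and group were the same on every array, so a dye effect of a single feature cannot be separated from a difference between the birds.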

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

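Among the 4 arrays, 1 value stood far from the other 3 for 5 of 132 genes and lists tested, against 6.6 that chance alone would give. SETDB1 was 1.01 on array 1 and 0.83 to 0.85 on the others. COX7A2L was 0.65 on array 3 and 0.54 to 0.55 on the others. ATP5H was 0.21 on array 1 and 0.39 to 0.43 on the others. TNNT3 was 0.31 on array 3 and 0.44 to 0.46 on the others. TMOD1 was -1.24 on array 1 and -1.06 to -1.03 on the others. In each case all 4 arrays had the same sign, and no list median stood apart in this way.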

How the results depend on the processing

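Chosen after the data were seen were the least variable centring, the neighbourhood subtraction, keeping the ceiling or ratio-of-1 features, the restriction to genes of lower SD, and the comparison of feature and gene calls with other assignments of the birds. Feature calls (1258) moved to 3431 without centring, 326 with neighbourhood subtraction, 389 with values on at least 3 arrays, 2494 with the unmoderated one-sample t statistic, 4269 at an unadjusted p under 0.05 with at least 1.3-fold, 3715 at an adjusted p under 0.10 and 346 against a 1.2-fold minimum. Gene calls (861) moved to 345 with neighbourhood subtraction, 537 with the 1.3-fold rule and 84 against a 1.2-fold minimum. Leaving out 1 array gave 120 to 142 feature calls and 4 to 404 gene calls (404, 4, 5 and 198 without array 1, 2, 3 and 4). Each of these fits loses the same degrees of freedom, so that loss leaves the distance between 4 and 404 open. Of 99 named genes that passed, 73, 4, 5 and 55 still passed without array 1, 2, 3 and 4. All 99 kept their sign each time, which was fixed in advance because each had the same sign on all 4 arrays. Under the other settings run, feature calls stayed between 924 and 1491, gene calls between 623 and 1186 (920 with features at a ratio of 1 kept).

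The share of higher calls among genes was 75.3%, and 44.9% with the least variable features at 0 and 0.782% without centring. Among features it was 70.0%, 39.9% and 4.90%. Of 23 lists, 8 were called with the preset correlation, 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05), 14 with fry, 1 among genes of lower SD (the slow sarcomere list, while the leukocyte list had too few members to be tested), 7 to 8 without 1 array, and 7 to 9 under the other settings run. Without centring, these genes that had been called higher had a negative ratio and did not pass: NDUFS3 -0.084, NDUFC2 -0.12, NDUFA9 -0.20, ATP5H -0.081, SDHD -0.23, IDH3A -0.10, PDHB -0.18, SUCLG2 -0.084, TFAM -0.029, SIRT3 -0.18, GAB1 -0.10, TNNT3 -0.027, PSMC1 -0.087, ATG3 -0.12, BNIP3 -0.093, ATG5 -0.14, DNAJA2 -0.0025, BAG3 -0.053, EIF3E -0.045, EIF2S1 -0.021, ME1 -0.12, HMGCS1 -0.15, HBA1 -0.0073 and FLT4 -0.12. The shift of all genes between these centrings is the cause of these turns. For the other changes the cause was not tested. The birds of each array can be assigned to the groups in 8 ways, the real one included, too few for a share under 0.05: in limma and camera the real one gave 1258 feature, 861 gene and 8 list calls, and the highest of the others 0, 0 and 5 (1202 features and 144 genes at an unadjusted p under 0.05). In each of these 3 counts 1 assignment, the real one, gave as many. A dye effect alike on all arrays would give the same outcome, since dye and group were the same on every array. Signal over background was not analysed here.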

Other observations

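The tests of a shift of all genes, of slow-fibre share, of saturation, of the least variable centring, of neighbourhood subtraction and of the slow list without MYH7 or MYH7B were chosen after the data were seen. So were the genes of this paragraph, single genes of which no list was fixed or tested, and all of which passed the limma test with the array median and with the least variable features at 0. ADPRHL1 (-1.34 ± 0.09, SD, n = 4), PTX3 (-1.25 ± 0.08), the LIM protein FHL2 (-0.78 ± 0.10), TIMD4 (-0.72 ± 0.08), the deiodinase DIO3 (-0.68 ± 0.25), MERTK (-0.59 ± 0.15) and nestin, NES (-0.59 ± 0.07), were lower. PRPS2, an enzyme of nucleotide synthesis (0.84 ± 0.10), the calmodulin gene CALM2 (0.74 ± 0.13), glutaredoxin, GLRX (0.67 ± 0.06), the mitochondrial ribosomal genes MRPL13 (0.62 ± 0.10) and MRPL3 (0.54 ± 0.09), and MID1IP1 (0.61 ± 0.12) were higher, and did not pass without centring.

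The first pattern is the fall of slow and cardiac-type sarcomere genes. A shift of all genes by centring is argued against by the list median, which lay at -0.75 relative to the median of all genes. After neighbourhood subtraction the list median was -0.66. That value does not decide on position on the array. The grid was inferred, and features 1 place apart correlated with r of only 0.03 to 0.05, so the subtraction could take little out of a single feature. The median of -0.88 with the least variable features at 0 decides nothing, since that centring lowers every gene alike, and a trend of the ratio with signal was not analysed here. A dye bias of single features cannot be told apart from a difference between the birds, since 0 arrays were dye-swapped. A lower share of slow fibres in the high-efficiency muscle samples, by biology or by the place sampled, is a candidate explanation. It is a hypothesis found and tested on the same genes: 76.9% of the measured slow members were called lower, against 28.6% of the 7 fast members. Of 24 listed fast genes only these 7 were measured, without a fast myosin heavy chain, which limits this contrast. Some members went the other way. MYH7 of the slow list stood at 0.72 ± 0.58, higher when adjusted over the list alone, and PVALB of the fast list fell (-0.96 ± 0.15). The slow list also holds cardiac and embryonic genes such as MYBPC3, TNNT2 and MYL4.

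The second pattern is the excess of higher over lower genes, with mitochondrial, ribosomal, translation and proteasome lists among the higher ones, for which no biological explanation was tested. Ratios of bright features held near 1 by saturation would follow each array's own median, so that array 1, whose deposited median was 0.34 above the mean of the others, would have list medians that much lower. The other arrays instead lay at -0.071 relative to array 1 (median over the 6 lists), although complexes II to V alone lay at 0.14. Centring and a real excess cannot be told apart, since the value placed at 0 sets the balance: 75.3% of calls were higher with the array median and 44.9% with the least variable features at 0. A trend of the ratio with signal was not analysed here. Shifting a whole array does not remove such a trend, so it stays open for these lists too. Of the 6 lists called higher, 4 had medians inside the central 95% of 10000 random lists matched on SD. The random lists matched to these 4 had medians of 0.09 to 0.17, so other genes of similar SD also lay above the array median. Why they did was not tested, and a small SD was not shown to mean a well-measured transcript. The ribosomal and proteasome lists lay above the central range (percentiles 99.5 and 99.2).

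The third pattern is how closely the pairs of birds matched for some genes. Over all 3494 genes the ratios of the arrays correlated with Pearson's r of 0.20 to 0.31 and Spearman's of 0.38 to 0.49, and the median SD of a gene was 0.17. PLN had an SD of 0.04 and MYH15 of 0.06 at ratios near -2.02 and -2.28. Both were named for a large mean ratio or a small p, and a small p favours a small SD. The mean of the 13 slow genes had an SD across arrays of 0.06, at percentile 26.9 of random lists matched on SD, but MYH7 and MYH7B moved in opposite directions in it (r = -0.99, n = 4 arrays). Whether slow fibre content differed between the pairs stays open: without MYH7 the percentile was 87.0, without MYH7B 0.70 and without both 42.1, and the 6 members over 2-fold lower had an SD of 0.19. Whether RNA of several birds was combined on an array is not given in the sources used here. The count of 1 bird of each group per array is therefore a reading of the labels.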
